A study of Arabidopsis thaliana with 9 samples.

How the data were processed

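Root tips of Arabidopsis thaliana Col-0, seu-3 and wox5-1 seedlings were collected 5 days after stratification, and 1 RNA sequencing library was made per sample, with 3 samples per genotype. Seedlings had been kept cold for 2 days and then grown upright with 1% sucrose, in days of 16 h light and 8 h dark. The length of tissue is about 1 mm in the series description and about 3 mm in the extraction protocol. That protocol also mentions sorted AGL42:GFP cells, which are not analysed here. Total RNA is named as the molecule; RNA selection and strandedness are not stated. The labels do not say that the samples of a genotype came from separate sowings or days, so p-values measure the spread between these samples. Replicate numbers were not taken to pair the samples.

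The deposited values are FPKM, fragments scaled by gene length and by the mapped fragments of the library, computed by the authors with Cufflinks. Per the labels the reads were aligned with Bowtie to TAIR10; versions, annotation and options are not given. The values were checked to be non-integer and non-negative, with sums between 794809 and 839181 per library. The smallest steps of FPKM times transcript length in genes with a single transcript gave approximate depths of 5.41 to 9.68 M fragments. The TAIR10.1 annotation in the reference was used for gene names, overlaps between genes, the transcript lengths behind these depths and the distance of genes from the mutated genes. Of the 33560 identifiers 32826, 16965 of them tested, had an entry there.

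Genes with a mean of at least 1 FPKM over the 9 libraries were tested, 17062 in all. FPKM were changed to log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, with 1 fit of genotype over the 9 libraries and an intensity trend in the variance prior. The contrasts were wox5-1 against Col-0, seu-3 against Col-0 and seu-3 against wox5-1, and a moderated F test covered all 3 genotypes. P-values were adjusted by Benjamini-Hochberg and calls were made at an adjusted p below 0.05; every adjusted p of a gene is from limma. WOX5 lay below the filter and so outside that fit, although a value from it had been planned; its change is a difference of group means with an exact permutation test. Fold changes in FPKM are ratios of group means. On simulated data made from these values, known changes of 1 log2 unit were recovered for 71.6% of genes in wox5-1 and 77.6% in seu-3, and changes of 0.5 for 20.9% and 17.9%. In each simulation 16862 of the 17062 genes were left unchanged. Adjusted p depend on how many genes change, and many more were called in the real contrasts, so these shares are not the power of those contrasts.

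Gene lists were tested with limma's camera, with a preset correlation between genes of 0.01, for lists with at least 3 tested members, adjusted over the lists of each contrast. Each list was also adjusted over its own members alone, and camera was repeated with a correlation estimated from the data. Genes to be named followed a rule: the 12 largest rises and the 12 largest falls in each mutant among called genes whose libraries do not overlap with Col-0, WOX5 and SEU, up to 4 called members per list and contrast by smallest p, or up to 2 in lists with none, up to 5 genes called in both mutants in the same and in opposite directions, and the 5 largest rises and falls between the mutants. The text prints a part of these, and genes outside the rule are said to have been named after their values were seen. Changes shared by both mutants were compared with independent lists and with 50 simulations of unchanged groups set against the same controls.

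Alternatives were a pseudocount of 0.1 FPKM, no filter, a mean of at least 5 FPKM, median-ratio scaling, quantile normalization, replicate number as a covariate, no trend in the variance prior, sample quality weights, only the 6 samples compared, a size threshold of 1 log2 unit and leaving out each library in turn. Tools for counts were not used, since the values are FPKM. Summaries and figures used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.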

Results

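Transcripts were measured by RNA sequencing in root tips of 5-day-old Arabidopsis thaliana seedlings of 3 genotypes, with 3 libraries of each. Col-0 is the wild type. The wox5-1 mutant lacks function of WOX5, which encodes a homeobox transcription factor made in the quiescent centre, the group of rarely dividing cells around which the root stem cells lie. The seu-3 mutant is altered in SEU (SEUSS), which encodes a transcriptional co-regulator that acts with LEUNIG. Per the labels the tissue was about 1 mm of the root tip in the series description and about 3 mm of root in the extraction protocol, and the data do not settle which. The sum of FPKM per library lay between 794809 and 839181, and the smallest steps in the values put the depth at roughly 5.41 to 9.68 M fragments per library, an approximation since the values are FPKM and not counts. All values below are mean FPKM ± SD over the 3 libraries of a genotype (n = 3), and changes are differences of log2(FPKM + 1), which understate the change of genes with a low FPKM. Of 33560 gene identifiers, 17062 had a mean of at least 1 FPKM over the 9 libraries and were tested. Among the genes named below, E2FA, SBE2.1, APL1, FRO3, ASFT, ROT3, BRL3, PLT3, REV, CYCD3;2, STK, MBF1C, SRO5 and AT5G04120 overlap another annotated gene, which leaves their values open to fragments of the neighbour.

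The extensin EXT3 was the most abundant transcript in every genotype, at 1.34% of the summed FPKM in Col-0, 1.65% in seu-3 and 1.46% in wox5-1. The 100 most abundant genes of each library held 29.6% ± 1.57 of the FPKM in seu-3, against 22.7% ± 0.121 in Col-0 and 21.4% ± 0.493 in wox5-1. Log values correlated across genes at 0.977 to 0.986 between libraries of the same genotype and at 0.846 to 0.935 between seu-3 and wox5-1 libraries; genes are not independent replicates. The first principal component, with 67.3% of the variance, separated seu-3 from wox5-1 with Col-0 between them. Relative to Col-0, the median change of all tested genes was 0.05 in wox5-1 and -0.24 in seu-3, so the medians of gene lists are given relative to the median of all tested genes. By the moderated F test of limma, 11195 genes (65.6%) differed among the 3 genotypes.

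WOX5 transcript was listed at 0 in all 3 wox5-1 libraries and at 0.301, 0.461 and 0.524 FPKM in the 3 Col-0 libraries. In seu-3 it was 0.0884 FPKM in replicate 1 and listed at 0 in replicates 2 and 3. These Col-0 values stand for roughly 2.41 to 4.26 fragments per library, so a low level in the mutants was not detectable at this depth. The value in seu-3 replicate 1 converts to 0.503 fragments, less than a whole fragment, so the conversion and the depth of that library are rough. The log2 change in wox5-1 was -0.51, with an exact two-sided permutation p of 0.1, the smallest that 3 libraries against 3 can give, and the gene lay below the 1 FPKM filter. Without that filter limma gave an adjusted p of 0.00462 in wox5-1, and a pseudocount of 0.1 FPKM put the log2 change there at -2.38. WOX5 fell in seu-3 too, by 0.47 on the log2 scale, with an exact permutation p of 0.1. Limma without the filter gave an adjusted p of 0.00558 for seu-3 against Col-0 and 0.649 for seu-3 against wox5-1. SEU transcript was 15.1 ± 3.14 FPKM in Col-0, 13.2 ± 0.156 in wox5-1 and 4.71 ± 0.513 in seu-3, where it fell by 1.48 on the log2 scale (SE 0.14, adjusted p = 0.000580) and was lower in each of the 3 libraries than in every Col-0 library. The exact two-sided permutation p of SEU in seu-3 was 0.1, again the smallest possible. SEU overlaps another annotated gene, and the deposited files do not say whether the libraries were strand-specific.

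**Figure D1:**
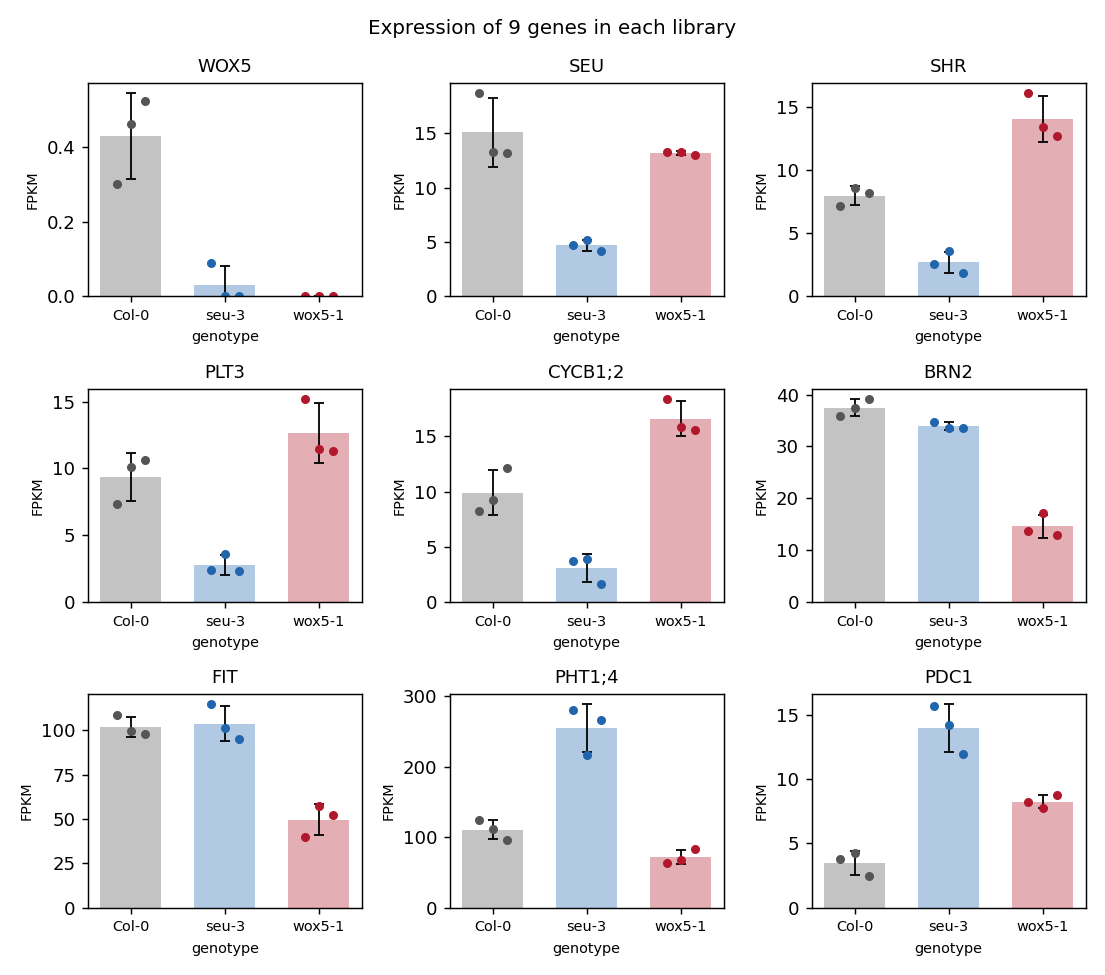
FPKM (vertical axes, each from 0) of 9 genes in the 3 genotypes (horizontal axes). Points are libraries, bars are means and error bars are SDs over 3 libraries. WOX5 was listed at 0 in all 3 wox5-1 libraries, and SEU averaged 4.71 FPKM in seu-3 against 15.1 in Col-0.

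The comparison of wox5-1 with Col-0 asks which transcripts of the root tip differ without WOX5. BRN2, a NAC transcription factor of root cap maturation, was 14.6 ± 2.27 FPKM in wox5-1 and 37.5 ± 1.63 in Col-0, 2.57-fold lower. FIT, the transcription factor that drives iron acquisition, was lower too, at 49.7 ± 8.94 against 102 ± 5.67 FPKM, as was the ferric reductase FRO2, at 4.50 ± 1.94 against 15.5 ± 5.00. The mitotic cyclin CYCB2;4 was 2.13-fold higher and the phosphoglucomutase PGM1 1.90-fold higher. SHR, a transcription factor that patterns the ground tissue and maintains the stem cell niche, rose from 7.96 ± 0.755 to 14.1 ± 1.81 FPKM (log2 change 0.75, adjusted p = 0.0169). In all, 2346 genes rose and 2307 fell at an adjusted p below 0.05, and 200 rose and 520 fell by at least 1 log2 unit. With median-ratio scaling the split was 2202 up and 2478 down. The 3 libraries of each genotype did not overlap for 50.2% of the tested genes, where chance gives 10%. The count of 4653 genes was 2648 without Col-0 replicate 1 (1007 up and 1641 down), 1523 without Col-0 replicate 2 (526 up and 997 down), 3017 without Col-0 replicate 3 (1349 up and 1668 down) and 1690 without wox5-1 replicate 1 (524 up and 1166 down). It was 7133 with sample quality weights (4043 up and 3090 down). Rises numbered 1427 and falls 2009 without wox5-1 replicate 3, and 1432 and 1754 with replicate number as a covariate (the replicate block). Omitting Col-0 replicate 1 ended the call of SHR (adjusted p = 0.0518), Col-0 replicate 2 that of CYCB2;4 (adjusted p = 0.0560) and wox5-1 replicate 1 those of SHR and CYCB2;4 (adjusted p from 0.0501 to 0.0689).

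The largest falls in wox5-1 were in DR4 (AT1G73330), a protein named for its repression by drought, from 44.1 ± 15.9 to 3.70 ± 1.59 FPKM (log2 change -3.27, SE 0.43, adjusted p = 0.00198), and in MLP329 (AT2G01530), of the major latex protein family, from 77.8 ± 24.7 to 8.43 ± 3.16 FPKM (log2 change -3.07, SE 0.32, adjusted p = 0.000859). APT4 (AT4G12440), an adenine phosphoribosyltransferase, was 35.6-fold lower, AT4G37950 18.3-fold and UMAMIT42 (AT5G40210), of a family of amino acid transporters, 12.98-fold. NRT2.6 (AT3G45060), of the nitrate transporter family, fell by 2.32 on the log2 scale. Of the 12 largest rises, AZI1 (AT4G12470), a lipid-transfer-like protein of systemic immunity, was alike in the 3 wox5-1 libraries, at 17.37 ± 0.618 FPKM against 3.12 ± 2.19 in Col-0 and 0.125 ± 0.216 in seu-3. NRPB12 (AT5G41010), a subunit of the nuclear RNA polymerases, rose from 21.5 ± 8.64 to 88.0 ± 17.3 FPKM. Another 7 of these 12 genes had their highest value in wox5-1 replicate 3. They include AGP23 (AT3G57690) and AGP40 (AT3G20865), arabinogalactan proteins known from pollen, and LP1 (AT2G38540), a lipid transfer protein. LP1 was 4.98, 1.32 and 21.9 FPKM, AGP23 was 3.34, 1.43 and 19.7 and AGP40 was 2.74, 0.997 and 26.7 in the 3 wox5-1 libraries, and all 3 genes were listed at 0 in the 6 other libraries. Over a list of 24 pollen genes, without those at 1 FPKM or more in a Col-0 library, the FPKM summed to 6.49, 3.34 and 47.6 in the 3 wox5-1 libraries and to between 0.790 and 1.58 in the 6 others. With all 24 genes the sum was 67.0 in wox5-1 replicate 3 and between 7.97 and 17.7 elsewhere. RBCS1A, a small subunit of Rubisco, was 28.6 FPKM in wox5-1 replicate 3 and between 1.75 and 6.10 FPKM elsewhere. Without wox5-1 replicate 3 these 7 genes fell below the filter, and the count of genes called was 3436. Removal of Col-0 replicate 1 ended the call of AGP40 (adjusted p = 0.0767), Col-0 replicate 2 those of LP1, AGP23 and AGP40 (adjusted p from 0.0546 to 0.0943) and Col-0 replicate 3 that of AGP40 (adjusted p = 0.0731). Without seu-3 replicate 1 the same was true of AGP40 (adjusted p = 0.0518) and without wox5-1 replicate 1 of LP1 and AGP40 (adjusted p from 0.050002 to 0.0715). With no filter on low values AGP40 did not pass (adjusted p = 0.0575).

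Of 25 gene lists chosen before the data were examined, 24 had at least 3 tested members, and 11 passed the camera set test in wox5-1 with its preset correlation; 0 passed with an estimated correlation. The G2/M list, genes of mitosis and cytokinesis, rose most: 12 of 24 tested members rose, 0 fell and 12 did not pass, or 19 rose adjusted over the list alone, and all 24 had a higher mean. Its median was 0.65 above that of all genes (camera adjusted p = 3.66e-05, and adjusted p = 0.603 with an estimated correlation). CYCB2;4 rose by 0.96 (SE 0.22, adjusted p = 0.0154) and CYCB1;4 by 0.86 (SE 0.20, adjusted p = 0.0165). In the S phase list, genes of DNA replication, 4 of 15 rose and 11 did not pass, also adjusted over the list alone, with E2FA, a transcription factor of replication genes, at 0.66, TSO2 at 0.66, PCNA2 at 0.64 and MCM4 at 0.65 (list median 0.42, camera adjusted p = 0.00535, and adjusted p = 0.603 with an estimated correlation). Among niche regulators, transcription factors and receptors of the stem cell niche, 7 of 15 rose and 8 did not pass, or 8 rose and 1 fell adjusted over the list alone (list median 0.45, camera adjusted p = 0.0107, and adjusted p = 0.344 with an estimated correlation). TMO7, an auxin-induced bHLH protein, rose by 0.65, RGFR2, a receptor of root growth peptides, by 0.67 and LHW, which promotes vascular divisions, by 0.71. TPL, a co-repressor on this list, was listed at 0 in wox5-1 replicate 1 and at 48.6 and 45.6 FPKM in the others. Of 12 starch synthesis genes 7 rose, 1 fell and 4 did not pass, or 9 rose and 1 fell adjusted over the list alone and 6 rose with median-ratio scaling (list median 0.38, camera adjusted p = 0.00682, and adjusted p = 0.446 with an estimated correlation). PGM1 rose by 0.77 (adjusted p = 0.00907), SBE2.1, a starch branching enzyme, rose by 0.61, and APL1, a subunit of ADP-glucose pyrophosphorylase named after its value was seen, changed by -0.44. The 12 risers of the G2/M list numbered 3 without Col-0 replicate 1, 0 without Col-0 replicate 2, 7 without Col-0 replicate 3, 7 without seu-3 replicate 1, 19 without seu-3 replicate 3, 0 without wox5-1 replicate 1 and 6 without wox5-1 replicate 3. The 4 risers of the S phase list numbered 0 without Col-0 replicate 1, Col-0 replicate 2 or wox5-1 replicate 1, 1 without Col-0 replicate 3, seu-3 replicate 1 or wox5-1 replicate 2, 2 without wox5-1 replicate 3, 7 without seu-3 replicate 2 and 9 without seu-3 replicate 3. Both lists stayed past camera with the preset correlation without each of the 9 libraries. Without seu-3 replicate 3, 1 niche regulator fell. The 7 niche risers numbered 4 without Col-0 replicate 1, 1 without Col-0 replicate 2 and 2 without wox5-1 replicate 1, and the 7 starch risers 4, 2 and 3 without these and 4 without wox5-1 replicate 2. Leaving out Col-0 replicate 1 ended the calls of E2FA, TSO2, PCNA2, MCM4 and APL1 (adjusted p from 0.0522 to 0.112), Col-0 replicate 2 those of CYCB2;4, CYCB1;4, E2FA, TSO2, PCNA2, MCM4, RGFR2, LHW and APL1 (adjusted p from 0.0560 to 0.122) and Col-0 replicate 3 those of TSO2, PCNA2, MCM4 and APL1 (adjusted p from 0.0655 to 0.0772). Without seu-3 replicate 1 the same was true of TSO2, PCNA2, MCM4 and APL1 (adjusted p from 0.05002 to 0.0677), without wox5-1 replicate 1 of CYCB2;4, CYCB1;4, E2FA, TSO2, PCNA2, MCM4, RGFR2, LHW and APL1 (adjusted p from 0.0501 to 0.159) and without wox5-1 replicate 2 of TSO2, PCNA2, MCM4 and APL1 (adjusted p from 0.0547 to 0.0669). Without wox5-1 replicate 3 the same was true of PCNA2 and MCM4 (adjusted p from 0.0504 to 0.0825). TSO2, PCNA2 and MCM4 also did not pass with no filter on low values (adjusted p from 0.0582 to 0.0735) or with a replicate block (adjusted p from 0.0509 to 0.0697), nor PCNA2 and MCM4 with a pseudocount of 0.1 FPKM (adjusted p = 0.0541 and 0.0740).

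Lower in wox5-1 were 7 of the lists. In columella and root cap, 5 of 9 tested members fell, 1 rose and 3 did not pass, also adjusted over the list alone (list median -0.71, camera adjusted p = 0.0137, and adjusted p = 0.344 with an estimated correlation). BRN2 changed by -1.31 (SE 0.11, adjusted p = 0.000353), its relative BRN1 by -0.95 and BFN1, a nuclease of dying root cap cells, by -1.01. SMB and CEL5, named after their values were seen, changed by -0.66 and -0.74, and PIN3, an auxin exporter of the columella and the stele, rose by 0.83. In iron deficiency, 8 of 12 fell, 1 rose and 3 did not pass, also adjusted over the list alone (list median -0.70, camera adjusted p = 0.000806, and adjusted p = 0.197 with an estimated correlation). FRO3, a reductase of mitochondria, changed by -1.47, FIT by -1.04 (SE 0.14, adjusted p = 0.00191) and FRO2 by -1.60, while PYE, a bHLH regulator of iron homeostasis named after its value was seen, rose by 0.64. In phosphate starvation, 6 of 10 fell and 4 did not pass, or 6 fell and 1 rose adjusted over the list alone (list median -0.61, camera adjusted p = 0.00966, and adjusted p = 0.344 with an estimated correlation). The phosphate transporter PHT1;1 went from 296 ± 11.98 to 164 ± 20.5 FPKM and the galactolipid synthase MGD3 from 6.38 ± 0.670 to 2.84 ± 0.700. Of 11 auxin response genes 3 fell and 8 did not pass, of 10 endodermis genes 3 fell and 7 did not pass, of 17 jasmonate and wounding genes 6 fell and 11 did not pass, and of 15 epidermis and root hair genes 3 fell and 12 did not pass, each also adjusted over the list alone; with median-ratio scaling 4 endodermis genes fell. The camera adjusted p was 0.00535 for auxin response, 0.00966 for endodermis, 0.0183 for jasmonate and wounding and 0.0183 for epidermis and root hair. With an estimated correlation these adjusted p were 0.344, 0.603, 0.344 and 0.603. IAA17, an auxin-induced repressor, changed by -0.51, ASFT, an enzyme of suberin synthesis, by -1.15, RSL2, a transcription factor of root hair growth, by -0.77, and TCH3, a touch-induced calmodulin-like protein, by -1.90. The epidermis and root hair list lost its call without Col-0 replicate 1 (adjusted p = 0.0870) and without wox5-1 replicate 1 (adjusted p = 0.0746). Without Col-0 replicate 2 the genes that fell numbered 5 in iron deficiency, 3 in phosphate starvation, 1 in auxin response, 1 in endodermis, 3 in jasmonate and wounding and 1 in epidermis and root hair. Without wox5-1 replicate 1 they numbered 5 in iron deficiency, 1 in auxin response, 1 in endodermis, 3 in jasmonate and wounding and 1 in epidermis and root hair. Without Col-0 replicate 1 they numbered 3 in jasmonate and wounding and 1 in epidermis and root hair, without Col-0 replicate 3 they numbered 5 in iron deficiency, 5 in auxin response and 1 in endodermis, and without wox5-1 replicate 2 they numbered 5 in endodermis. Without seu-3 replicate 3, 1 phosphate starvation gene rose. Omitting Col-0 replicate 1 ended the calls of CEL5 and IAA17 (adjusted p from 0.0520 to 0.0691), Col-0 replicate 2 those of CEL5, PYE and IAA17 (adjusted p from 0.0605 to 0.0859) and wox5-1 replicate 1 those of SMB and PYE (adjusted p from 0.0556 to 0.0902). Without wox5-1 replicate 3 the same was true of PYE (adjusted p = 0.0533).

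The other lists did not pass in wox5-1, several with members that changed. Among genes of auxin synthesis and transport 5 of 13 rose, or 4 with median-ratio scaling, all of them PIN exporters, with PIN3 at 0.83 and PIN7 at 0.72 (camera adjusted p = 0.151). Of 17 gibberellin and brassinosteroid genes 4 rose and 4 fell, with the gibberellin synthesis genes GA20OX2 at 1.297 and GA3OX1 at 0.97, the brassinosteroid synthesis gene ROT3 at -0.91 and the receptor BRL3, named after its value was seen, at -0.65 (camera adjusted p = 0.898). In xylem 3 of 12 rose, with PHB at 0.77 (camera adjusted p = 0.237). In hypoxia 2 of 7 rose and 1 fell, the pyruvate decarboxylase PDC1 at 1.06, HRE2 at 0.76 and the haemoglobin HB1 at -0.90 (camera adjusted p = 0.435). SHR was the single riser of 12 genes in the SHR-SCR network, where 2 rose with median-ratio scaling (camera adjusted p = 0.124), and 1 of 4 D-type cyclins rose (camera adjusted p = 0.154). AGL17 fell among 4 MADS-box genes (log2 change -1.20, camera adjusted p = 0.287), 2 of 5 heat shock genes fell, with HSP70-4 at -1.45 (camera adjusted p = 0.287), and 4 of 16 green tissue genes fell, or 3 adjusted over the list alone, with PSBO1 at -0.71 (camera adjusted p = 0.117, and past the threshold at 0.0451 without Col-0 replicate 1 and at 0.000234 without wox5-1 replicate 3; adjusted p = 0.671 with an estimated correlation). Members that passed numbered 0 of 6 in the SEU complex (camera adjusted p = 0.893), 0 of 7 in cytokinin response (0.612) and 0 of 3 in phloem (0.893). Of 7 reference genes, ACT2 changed by -0.32 (camera adjusted p for the list = 0.561), and 0 passed adjusted over the list alone. Of the WOX family only WOX12 and WOX13 were tested, too few for camera, and WOX12 rose by 0.80. The other counts in this paragraph were equal adjusted over the list alone. The 5 PIN rises numbered 3 without Col-0 replicate 1 and 2 without Col-0 replicate 2, Col-0 replicate 3 or wox5-1 replicate 1, while 3 auxin synthesis and transport genes rose and 3 fell without wox5-1 replicate 3. Without Col-0 replicate 2 or wox5-1 replicate 1 the falls in gibberellin and brassinosteroid numbered 2, the rises in xylem 1 and the rises in D-type cyclins 0; the latter numbered 0 also without Col-0 replicate 1, Col-0 replicate 3, seu-3 replicate 1 or wox5-1 replicate 3. Without Col-0 replicate 1 the falls in gibberellin and brassinosteroid numbered 2, and the falls in green tissue numbered 1 without Col-0 replicate 2 and 2 without Col-0 replicate 3, seu-3 replicate 1 or wox5-1 replicate 1. The falls in heat shock numbered 1 without Col-0 replicate 1, Col-0 replicate 2, wox5-1 replicate 2 or wox5-1 replicate 3. In the SHR-SCR network 2 rose without seu-3 replicate 2, 3 rose without seu-3 replicate 3, 0 rose without Col-0 replicate 1 or wox5-1 replicate 1 and 1 fell without wox5-1 replicate 2. In the SEU complex 1 rose without seu-3 replicate 2 or seu-3 replicate 3, in hypoxia 2 fell without seu-3 replicate 2 or wox5-1 replicate 2, and in green tissue 2 rose without wox5-1 replicate 2. Without wox5-1 replicate 3 only 12 green tissue genes were tested instead of 16, and 6 of them fell. The camera value of green tissue without that library is therefore for a changed set of genes. Removal of Col-0 replicate 1 ended the calls of SHR and ACT2 (adjusted p from 0.0518 to 0.0948), Col-0 replicate 2 those of ACT2 and WOX12 (adjusted p from 0.0743 to 0.106) and Col-0 replicate 3 those of ACT2 and WOX12 (adjusted p from 0.0577 to 0.0628). Without seu-3 replicate 1 the same was true of ACT2 (adjusted p = 0.0584), without wox5-1 replicate 1 of SHR and ACT2 (adjusted p from 0.0689 to 0.0943) and without wox5-1 replicate 2 of ACT2 (adjusted p = 0.0633). Without wox5-1 replicate 3 the same was true of WOX12 (adjusted p = 0.0657). With a replicate block WOX12 (adjusted p = 0.0530) and ACT2 (0.0674) did not pass, nor did ACT2 with no filter on low values (0.0730) or with quantile normalization (0.105).

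The comparison of seu-3 with Col-0 asks which transcripts differ when SEU is altered. The cyclin CYCB1;2 was lower in seu-3, at 3.09 ± 1.26 FPKM against 9.88 ± 2.04 in Col-0, SHR was 2.68 ± 0.866 against 7.96 ± 0.755 and PLT3, an AP2 transcription factor of the niche, was 2.77 ± 0.725 against 9.35 ± 1.79. The phosphate transporter PHT1;4 was higher, at 255 ± 34.0 against 111 ± 14.1 FPKM, as was PDC1, at 14.0 ± 1.88 against 3.496 ± 0.943. OSM34 (AT4G11650), an osmotin-like protein, was 17.59 ± 3.04 FPKM in seu-3 and at or under 0.146 FPKM in each Col-0 library. In all, 1136 genes rose and 5830 fell (83.7% of those called), and 184 rose and 1395 fell by at least 1 log2 unit. With median-ratio scaling, which moves the median of all genes from -0.24 to -0.01, 3021 rose and 3018 fell, and 2812 of the falls were called only as deposited. The libraries of both genotypes did not overlap for 56.3% of the tested genes, where chance gives 10%. The count of 6966 genes was 4575 without seu-3 replicate 3 (681 up and 3894 down), 4630 with quantile normalization (2280 up and 2350 down) and 11040 with sample quality weights (2459 up and 8581 down). Rises numbered 701 and falls 4106 without Col-0 replicate 3.

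The largest rises in seu-3 were OSM34 (log2 change 4.14, SE 0.16, adjusted p = 5.64e-06), AT4G26880 at 5.95-fold, AT2G10940 at 10.4-fold and IAMT1 (AT5G55250), an enzyme that methylates the auxin indole-3-acetic acid, from 23.8 ± 4.33 to 138 ± 16.9 FPKM (log2 change 2.49, SE 0.16, adjusted p = 9.55e-05). CEL3 (AT1G71380), a cellulase, was 4.92-fold higher and LEA4-5 (AT5G06760), a late embryogenesis abundant protein, 6.56-fold. Several of the largest falls differed widely between Col-0 libraries: AT3G15450 was 112, 557 and 1095 FPKM in the 3 Col-0 libraries and 18.7, 20.7 and 10.7 in seu-3 (log2 change -4.58, SE 0.79, adjusted p = 0.00438). DIN10 (AT5G20250) went from 274 ± 169.7 to 27.8 ± 3.59 FPKM, and ERD5 (AT3G30775), proline dehydrogenase, from 345 ± 199 to 37.8 ± 4.83. HEI10 (AT1G53490), a ubiquitin ligase of meiotic crossovers, was alike in the Col-0 libraries and 21.9-fold lower, at 0.465 ± 0.278 against 10.2 ± 0.580 FPKM (log2 change -2.95, SE 0.15, adjusted p = 3.24e-05). AT3G15450, DIN10 and HEI10 overlap other annotated genes, which leaves their values open to fragments of the neighbour.

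In seu-3, 4 of 24 lists passed camera with the preset correlation and 0 with an estimated correlation. In the G2/M list 21 of 24 fell and 3 did not pass, or 23 fell adjusted over the list alone and 18 with median-ratio scaling (list median -0.80, camera adjusted p = 5.90e-05, and adjusted p = 0.878 with an estimated correlation). CYCB1;2 changed by -1.45 (SE 0.23, adjusted p = 0.00363), CYCA2;4 by -1.33 and CYCB2;3 by -1.18. All 15 S phase genes fell, also adjusted over the list alone, and 8 of them with median-ratio scaling (list median -0.53, camera adjusted p = 0.00436, and adjusted p = 0.878 with an estimated correlation). The replication licensing genes MCM5, MCM6 and CDT1A changed by -0.99, -0.89 and -0.83. In phosphate starvation 6 of 10 rose and 4 did not pass, or 8 rose and 1 fell adjusted over the list alone and 8 rose with median-ratio scaling (list median 0.73, camera adjusted p = 8.08e-06, and adjusted p = 0.160 with an estimated correlation). PHT1;4 rose by 1.19 (SE 0.14, adjusted p = 0.00152), the phosphatase PS2 by 0.96 and the ribonuclease RNS1 by 0.64. In hypoxia 3 of 7 rose and 4 did not pass, also adjusted over the list alone, and 6 rose with median-ratio scaling (list median 0.57, camera adjusted p = 0.000222, and adjusted p = 0.120 with an estimated correlation). PDC1 rose by 1.75 (SE 0.17, adjusted p = 0.000580) and SRO5 by 1.00. The 15 falls of the S phase list numbered 7 without Col-0 replicate 3, 9 without seu-3 replicate 1 and 8 without seu-3 replicate 3, and the 6 rises in phosphate starvation numbered 3 without each of these. Without wox5-1 replicate 2, 1 phosphate starvation gene fell.

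Of all 17062 tested genes 5830 fell in seu-3, so a list can hold many falls for that reason alone. The lists below held members that fell without passing camera. Of 15 niche regulators 8 fell, or 8 fell and 1 rose with median-ratio scaling, with PLT3 at -1.46 (SE 0.19, adjusted p = 0.00186), TMO5 at -1.02 and RGFR3 at -1.06 (camera adjusted p = 0.271). In the SHR-SCR network 5 of 12 fell, or 2 with median-ratio scaling, with SHR at -1.31 and MGP at -1.16 (camera adjusted p = 0.572). Of 13 genes of auxin synthesis and transport 8 fell, or 4 with median-ratio scaling, and 1 rose, with LAX2 at -1.26, PIN7 at -0.80 and YUC3, named after its value was seen, at 0.91 (camera adjusted p = 0.572). In auxin response 4 of 11 fell, or 5 adjusted over the list alone and 3 with median-ratio scaling, and 2 rose, with GH3.5, an enzyme that conjugates auxin, at -1.38 and IAA17 at 0.54 (camera adjusted p = 0.912). In iron deficiency 6 of 12 fell, or 4 fell and 2 rose with median-ratio scaling, with the nicotianamine synthase NAS4 at -1.75 and FRO2 at -1.38, while FIT was 104 ± 9.97 FPKM in seu-3 (camera adjusted p = 0.866). In jasmonate and wounding 6 of 17 fell and 1 rose, or 4 fell and 4 rose with median-ratio scaling, with TCH3 at -1.79 and TCH4 at 0.97 (camera adjusted p = 0.572). In epidermis and root hair 3 of 15 fell and 2 rose, or 1 fell and 7 rose with median-ratio scaling, with RSL2 at -1.40 (camera adjusted p = 0.0614), and the list passed without Col-0 replicate 1 (0.0220), seu-3 replicate 2 (0.0186), wox5-1 replicate 1 (0.0286) or wox5-1 replicate 3 (0.0484), with adjusted p = 0.878 for all libraries with an estimated correlation. In columella and root cap 3 of 9 fell and 1 rose, or 2 fell and 3 rose with median-ratio scaling, SMB at -1.01 and BFN1 at 0.94 (camera adjusted p = 0.792). Without Col-0 replicate 2 or seu-3 replicate 3 the falls in the SHR-SCR network numbered 3, and without Col-0 replicate 1, Col-0 replicate 2, seu-3 replicate 1 or seu-3 replicate 3 those in auxin synthesis and transport numbered 5. Without Col-0 replicate 3 those in iron deficiency numbered 3, and without seu-3 replicate 1 those in jasmonate and wounding numbered 3. Without Col-0 replicate 1, 4 jasmonate and wounding genes fell and 3 rose, and 2 columella and root cap genes rose. The rises in epidermis and root hair numbered 0 without Col-0 replicate 2, Col-0 replicate 3 or seu-3 replicate 3, 1 without seu-3 replicate 1 and 6 without wox5-1 replicate 1, and those in auxin response 1 without Col-0 replicate 3 or seu-3 replicate 3. Leaving out Col-0 replicate 2 ended the call of YUC3 (adjusted p = 0.0511).

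The remaining lists in seu-3 gave camera adjusted p of 0.572 for xylem, where 5 of 12 fell, or 3 with median-ratio scaling, with REV at -0.80, and 0.572 for gibberellin and brassinosteroid, where 6 of 17 fell and 1 rose, or 2 fell and 5 rose with median-ratio scaling, with GAI at -0.80. Of 12 starch synthesis genes 3 fell, or 0 with median-ratio scaling, with PGM1 at -0.55 (camera adjusted p = 0.547). Of 4 D-type cyclins 2 fell, CYCD3;3 at -1.17 and CYCD3;2 at -0.94 (camera adjusted p = 0.635). Of 4 MADS-box genes 3 fell, or 1 with median-ratio scaling, and STK, known from ovules, rose by 0.83 to 2.71 ± 0.180 FPKM (camera adjusted p = 0.914; the median and mean of this list were negative and the camera direction was up). Of 6 SEU complex genes SEU alone fell (camera adjusted p = 0.815), though with median-ratio scaling 2 others rose. CVP2 fell in phloem by 1.07 on the log2 scale, among 3 genes (camera adjusted p = 0.795). In endodermis 1 of 10 fell, or 0 adjusted over the list alone and 0 with median-ratio scaling (camera adjusted p = 0.815). In heat shock 1 of 5 rose, MBF1C by 0.85, and 1 fell, or 0 fell with median-ratio scaling (camera adjusted p = 0.517). In green tissue 1 of 16 fell, or 2 rose and 0 fell with median-ratio scaling (camera adjusted p = 0.347), and in cytokinin response 0 of 7 passed (camera adjusted p = 0.796). Of 7 reference genes TIP41L changed by -0.56, and with median-ratio scaling 1 rose and 1 fell (camera adjusted p = 0.795), and WOX12 rose by 0.66 of the 2 tested WOX genes. Before the median of all tested genes is subtracted, some list medians turned from negative to positive with median-ratio scaling. These were the SEU complex, columella and root cap, cytokinin response, gibberellin and brassinosteroid, phloem, jasmonate and wounding, heat shock, green tissue and the reference genes. Relative to all tested genes, the medians of these lists were positive as deposited. Counts in seu-3 with no second value were equal adjusted over the list alone. The falls in gibberellin and brassinosteroid numbered 4 without Col-0 replicate 1 or Col-0 replicate 3, where 3 and 0 rose, 3 without Col-0 replicate 2 or seu-3 replicate 3 and 5 without wox5-1 replicate 1, where 2 rose. The falls in xylem numbered 2 without Col-0 replicate 3 and 3 without seu-3 replicate 3, those in starch synthesis 1 without either of these and 5 without seu-3 replicate 2, and those in MADS-box genes 0 without either and 1 without Col-0 replicate 1. In gibberellin and brassinosteroid 0 rose without Col-0 replicate 2, seu-3 replicate 1 or seu-3 replicate 2. Without seu-3 replicate 2, 4 D-type cyclins and 2 SEU complex genes fell. In endodermis 3 fell without Col-0 replicate 1 and 0 without Col-0 replicate 2, Col-0 replicate 3 or seu-3 replicate 3, and in heat shock 0 fell without Col-0 replicate 2, Col-0 replicate 3 or any 1 of the seu-3 libraries. In green tissue 2 fell without Col-0 replicate 1 or wox5-1 replicate 3 and 0 without Col-0 replicate 2, in cytokinin response 1 fell without Col-0 replicate 1, Col-0 replicate 2 or seu-3 replicate 3, and 1 reference gene rose without seu-3 replicate 2 or wox5-1 replicate 1. Omitting Col-0 replicate 2 ended the calls of PGM1 and WOX12 (adjusted p from 0.0562 to 0.0746), Col-0 replicate 3 those of PGM1 and WOX12 (adjusted p from 0.0596 to 0.107) and seu-3 replicate 1 that of WOX12 (adjusted p = 0.0527). Without seu-3 replicate 2 the same was true of WOX12 (adjusted p = 0.0733) and without seu-3 replicate 3 of PGM1 and WOX12 (adjusted p from 0.0569 to 0.0838). PGM1 did not pass with median-ratio scaling (adjusted p = 0.0798) or quantile normalization (0.378), nor WOX12 with no filter on low values (0.0537) or with a replicate block (0.0648).

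**Figure D2:**
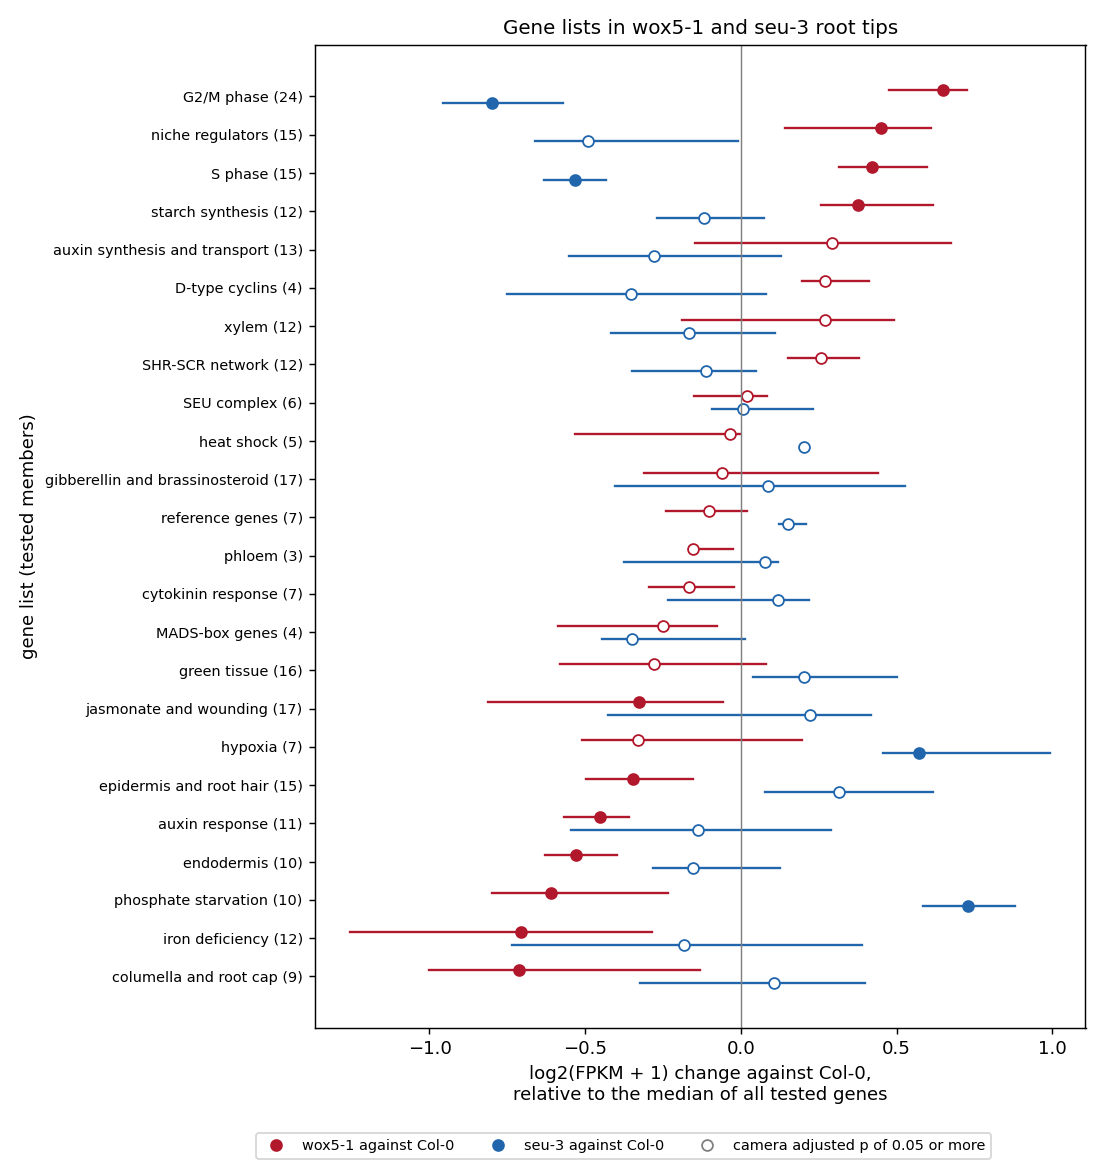
Median log2(FPKM + 1) change against Col-0 of the tested members of 24 gene lists (horizontal axis), relative to the median of all tested genes, in wox5-1 (red) and seu-3 (blue). Lines span the quartiles of the members, filled points passed camera with the preset correlation and 0 lists passed with an estimated correlation. The G2/M list lay at 0.65 in wox5-1 and at -0.80 in seu-3.

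Set against each other directly, seu-3 and wox5-1 differed in the cell cycle: all 24 G2/M genes and all 15 S phase genes were lower in seu-3, with CYCA2;4 at 1.42 ± 0.437 FPKM in seu-3 and 8.37 ± 1.09 in wox5-1. SHR was 2.68 ± 0.866 FPKM in seu-3 and 14.1 ± 1.81 in wox5-1, 5.24-fold lower in seu-3. PHT1;4 was 255 ± 34.0 against 71.7 ± 10.1 FPKM and AT5G04120 was 116 ± 24.2 against 6.31 ± 2.51, both higher in seu-3. In this contrast, which is also the test of whether the effects of both mutations differ, 3400 genes were higher and 7613 lower in seu-3 (69.1% lower), or 5471 and 5515 with median-ratio scaling. The libraries did not overlap for 71.0% of the tested genes, against 10% by chance. By the rule for named genes, the largest rises were OSM34 (log2 difference 4.14), AT5G04120 (4.03), AT5G26270 (3.89), AT2G03980 (3.80) and AT4G37950 (3.76). The largest falls were AT3G15450 (-4.57), AZI1 (-4.05), ATCTH (-4.02), HEI10 (-3.40) and AT2G28790 (-3.33).

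Of 24 lists, 6 passed camera between seu-3 and wox5-1 with the preset correlation and 0 with an estimated correlation. The G2/M list (median -1.50, camera adjusted p = 1.46e-05), the S phase list (median -1.07, camera adjusted p = 0.00133) and the starch synthesis list (10 of 12 lower, median -0.45, camera adjusted p = 0.0348) were lower in seu-3. With an estimated correlation their adjusted p were 0.605, 0.618 and 0.599. Higher in seu-3 were phosphate starvation (8 of 10 higher, median 1.33, camera adjusted p = 7.33e-05), hypoxia (5 of 7 higher and 1 lower, median 0.95, camera adjusted p = 0.0104) and epidermis and root hair (8 of 15 higher and 3 lower, median 0.64, camera adjusted p = 0.0269). With an estimated correlation their adjusted p were 0.262, 0.262 and 0.618, and the epidermis and root hair list did not pass with median-ratio scaling (adjusted p = 0.0553). These counts were equal adjusted over the list alone, and with median-ratio scaling 0 hypoxia genes and 0 epidermis and root hair genes were lower, 9 of the latter were higher and 8 starch synthesis genes were lower. PHT1;4 differed by 1.82 (adjusted p = 4.70e-05), HB1 by 1.03, COBL9, a root hair gene, by 0.99 and PGM1 by -1.32. Among niche regulators 11 of 15 were lower and AGL42, named after its value was seen, was higher by 0.93 (camera adjusted p = 0.0538, and adjusted p = 0.593 with an estimated correlation). The niche list passed with median-ratio scaling (adjusted p = 0.0194; 11 lower and 2 higher) and without Col-0 replicate 2 (adjusted p = 0.0428), Col-0 replicate 3 (0.0454), seu-3 replicate 1 (0.0178), seu-3 replicate 2 (0.0369), seu-3 replicate 3 (0.0398), wox5-1 replicate 1 (0.0238) or wox5-1 replicate 2 (0.0370). Endodermis passed without wox5-1 replicate 2 (adjusted p = 0.0370) and green tissue without wox5-1 replicate 3 (adjusted p = 0.00119), and with all libraries and an estimated correlation their adjusted p were 0.681 and 0.677. Without wox5-1 replicate 3 only 12 green tissue genes were tested instead of 16, with 8 higher and 1 lower against 2 and 2. Camera adjusted p lay between 0.0693 for green tissue and 0.788 for gibberellin and brassinosteroid in the other 17 lists. Before the median of all tested genes is subtracted, the medians of cytokinin response and MADS-box genes were negative as deposited and positive with median-ratio scaling. Relative to all tested genes they were 0.24 and 0.26 as deposited. Without seu-3 replicate 1 AGL42 fell below the filter, and without wox5-1 replicate 3, 2 niche regulators were higher. In hypoxia 0 genes were lower without seu-3 replicate 1, seu-3 replicate 2, wox5-1 replicate 2 or wox5-1 replicate 3. Removal of wox5-1 replicate 1 ended the call of AGL42 (adjusted p = 0.0776).

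Both mutants were set against the same Col-0 libraries, and 2318 genes were called in both. MLP329, AT3G59930 and NRT2.6 fell in both: AT3G59930 was 59.4 ± 15.9 FPKM in Col-0, 7.12 ± 2.42 in seu-3 and 7.27 ± 0.0786 in wox5-1. AZI1, AT2G03980 and XTH9, an enzyme of cell wall xyloglucan, changed in opposite directions: XTH9 was 6.92 ± 1.91 FPKM in Col-0, 1.94 ± 1.17 in seu-3 and 20.3 ± 4.46 in wox5-1. Of the 2318 genes, 51 rose in both, 472 fell in both, 1484 rose in wox5-1 and fell in seu-3 and 311 fell in wox5-1 and rose in seu-3, so 77.4% went in opposite directions. Independent lists of these sizes would share 156, 788, 802 and 154 genes in the same order. With median-ratio scaling the counts were 107, 284, 895 and 792. Across genes the changes in both mutants correlated at -0.26, where groups with no change against shared controls gave 0.50 (0.44 to 0.53 in 50 simulations), and the covariance was -0.07 against 0.02. The count of 2318 was 1067 without Col-0 replicate 1, 509 without Col-0 replicate 2, 969 without Col-0 replicate 3, 1369 without seu-3 replicate 1 and 794 without wox5-1 replicate 1. The share in opposite directions was lowest, 52.8%, without Col-0 replicate 1. Leaving out Col-0 replicate 2 ended the call of XTH9 (adjusted p = 0.0559) and wox5-1 replicate 1 that of XTH9 (adjusted p = 0.0569).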

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

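The test of library scaling and the 2 tests of the share of meristem in the tips were chosen only after the cell cycle result was seen, and the bounds of 2 SE in these tests and of 0.1 times in the pollen test were set after their values were seen. The SEs of list medians in these tests are over the genes of a list, which are not independent, and not over libraries. Between the mutants, the change of the G2/M list in seu-3 minus that in wox5-1 had a median of -1.77 and that of the S phase list -1.33, or -1.50 and -1.07 relative to the median of all tested genes, which differed by -0.27. Scaling by the authors, as 1 factor for all genes of a library, would leave the G2/M list near the median of all genes. The smaller of its 2 distances, in wox5-1, was 0.648 (SE 0.0532), which argues against such a factor as the whole cause. This distance is the list median already reported, so it adds no separate support for the cell cycle result. A larger share of meristem in the wox5-1 tips and an effect of the genotype on division cannot be told apart. Of the lists of mature tissue, root hair maturation lay at -0.459 (SE 0.0661) and endodermal barriers at -0.528 (SE 0.0896). The endodermis list reported above had the same median, so endodermal barriers adds no separate support. Xylem secondary wall lay at -0.199 (SE 0.122), within 2 SE of 0. By library, root hair maturation ran from -0.750 to -0.177 in wox5-1 and from -0.156 to 0.125 in Col-0. Endodermal barriers ran from -0.682 to -0.0718 in wox5-1 and from -0.380 to 0.294 in Col-0, so these ranges overlapped. Those of xylem secondary wall, -0.350 to 0.0601 in wox5-1 and -0.138 to 0.118 in Col-0, overlapped too. For seu-3, a smaller share and an effect of the genotype cannot be told apart either: root hair maturation lay at 0.590 (SE 0.136), while endodermal barriers at -0.261 (SE 0.164) and xylem secondary wall at 0.0261 (SE 0.104) lay within 2 SE of 0. The gap of 0.851 (SE 0.213, over genes) between the first pair ran from 0.419 to 1.35 over the seu-3 libraries and from -0.450 to 0.505 over those of Col-0, so the ranges overlapped.

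The difference itself also passed the test for starch synthesis (median -0.714, or -0.45 relative to all tested genes), epidermis and root hair (0.372, or 0.64), hypoxia (0.685, or 0.95) and phosphate starvation (1.07, or 1.33), each with the preset correlation and none with an estimated correlation (0 lists).

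Of 24 pollen genes, 16 lay below the filter, and 15 of these had a wox5-1 mean above every one of the 6 other libraries. RNA from pollen or flowers may be present in the wox5-1 libraries: 11 genes were above 0 in wox5-1 replicate 3 with the 6 other libraries below 0.1 times that value. The most abundant of the list in that library were AT3G14040 at 12.4 FPKM and AGP6 at 11.8 FPKM, and SEP3 at 1.15, PI at 1.02 and RBCS1A at 28.6 FPKM were higher there than in the other libraries. A sum was taken without the 6 of the 24 genes that reached 1 FPKM in a Col-0 library. It was 6.49, 3.34 and 47.6 FPKM in the 3 wox5-1 libraries and 0.790 to 1.58 in the 6 others. Leaving out genes by their Col-0 values lowers the Col-0 sums by itself, so this gap is partly set by the selection. With all 24 genes the sums of wox5-1 replicates 1 and 2 were 16.4 and 15.5 FPKM, within the 10.6 to 17.7 of Col-0. Only the sum of replicate 3, at 67.0, lay apart, which goes with RNA from pollen or flowers in that library. The 11 of 24 genes fell short of the majority asked for, though the 24 still held the 6 genes that reached 1 FPKM in a Col-0 library. Of the 24, 23 were above 0 in wox5-1 replicate 3, 17 were highest there and 10 were at 0 in all 6 other libraries. Pollen RNA and transcription of these genes in wox5-1 roots cannot be told apart by these values, which rest mostly on that library.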

How the results depend on the processing

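Leaving out libraries for the gene lists and their members was chosen only after the data were seen; the other alternatives were planned. Of 320 named gene results past the threshold, 206 passed in every setting in which the gene was tested. Of the 320, 99 were lost without at least 1 library and 75 in another setting, and 0 reversed. A gene below the filter of a setting was not tested there and was not counted as lost. The cause was not tested for any change below.

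With an estimated correlation 0, 0 and 0 lists passed in wox5-1, seu-3 and between the mutants, against 11, 4 and 6. Genes called in wox5-1 numbered 7133 with sample quality weights and 720 with a size threshold of 1, and 1523 to 5628 without 1 library: 2648, 1523 and 3017 without Col-0 replicates 1, 2 and 3, and 1690 without wox5-1 replicate 1. In seu-3 they numbered 4630 with quantile normalization, 11040 with weights and 1579 with the size threshold, and 4575 to 7117 without 1 library, the lowest without seu-3 replicate 3. The fit of the weights reported a convergence tolerance that was not reached. Between the mutants they numbered 4207 with the size threshold and 9710 to 11008 without 1 library, and by the F test 9623 to 11087. Shared changes numbered 1395 with a replicate block and 509 to 2870 without 1 library. That replicate block gave 3186, 5955, 10499 and 10296 genes for the 4 tests. The deviations of libraries from their genotype means correlated at -0.26 to 0.19 between libraries of the same number. Lists past the threshold numbered 10 to 12, 4 to 5 and 6 to 8 without 1 library.

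WOX5 passed without the filter (log2 change -0.51, adjusted p = 0.00462), with -0.58 to -0.46 without 1 library and permutation p of 0.1 to 0.25 over its other alternatives; the stricter filter, no trend and weights gave no value, as it lay below the filter. SEU kept its call, at -1.56 to -1.33 without 1 library.

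These changed direction, all without a call. Median-ratio scaling: the SEU complex (0.0191) and MADS-box genes (-0.36, by camera) in seu-3 and WOX12 between the mutants (0.12). Quantile normalization: WOX12 (0.26) and CKX5 (0.14) between the mutants. Quality weights: CVP2 in wox5-1 (0.0517). Without 1 library, camera or the fitted value turned for: SEU complex (-0.0706 to 0.0374), gibberellin and brassinosteroid (-0.0958 to 0.0733), phloem (-0.20 to -0.0263) and CVP2 (-0.19 to 0.0216) in wox5-1; MADS-box genes (-0.50 to -0.19), auxin response (-0.29 to 0.12), endodermis (-0.24 to -0.0407), iron deficiency (-0.31 to -0.0651) and cytokinin response (-0.0526 to 0.21) in seu-3; cytokinin response (0.0682 to 0.33) and WOX12 (-0.24 to 0.0215) between the mutants.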

Other observations

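The 2 clock tests were chosen only after 4 clock genes had been seen to differ in wox5-1, and those 4 were left out of them. Genes of the circadian clock differed between wox5-1 and Col-0: CCA1, a morning gene, was 4.11 ± 0.545 FPKM in Col-0, 3.07 ± 0.173 in seu-3 and 0.536 ± 0.280 in wox5-1 (log2 change -1.74, limma adjusted p = 0.000439), and LNK2 changed by -1.31 and RVE8 by -0.94. The evening gene FKF1 rose by 0.99, ELF4 by 0.57 and TOC1 by 0.40. The median of 8 evening genes lay 0.914 above that of 8 morning genes in wox5-1 (exact permutation p = 0.00311) and at -0.16 in seu-3 (exact permutation p = 0.794); these permutations run over genes of a shared circuit, not over libraries. In seu-3, 7 of the 16 also passed the threshold, 3 morning and 4 evening genes, all lower, where 40.8% of all tested genes passed. RVE1 changed by -1.31, GRP8 by -1.27, RVE7 by -1.07 and TOC1 by -0.53. Another time of collection for wox5-1 is a candidate explanation that these values go with; an effect of the genotype on the clock stays open and was not tested. That clock genes lay at the noise level is argued against for the 7 of the 16 that passed the threshold in wox5-1, and for these alone. The test asked for only 3 such genes, a low bound, since 27.3% of all tested genes passed. Genes below the filter had also been left out beforehand.

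Called genes were not more frequent near the mutated gene. Within 1 Mb of SEU 46 of 131 tested genes were called in seu-3 (odds ratio 0.779, 95% confidence interval 0.531 to 1.13), and within 1 Mb of WOX5 109 of 422 in wox5-1 (odds ratio 0.928, interval 0.737 to 1.16).

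In splits of the 6 libraries the real one alone, 1 of 10, gave as many genes in each contrast, which is too few splits for a share under 0.05. The real counts were 4653, 6966 and 11013 and the highest of the others 13, 1 and 1. Over 100 drawn of 280 splits of the 9 libraries, 1, the real one with 11195 genes, gave as many, and the highest other was 6176. A random assignment of the libraries to groups is thus an unlikely source of the count for the 3 genotypes. Anything else shared by the libraries of a genotype, such as a time of collection, would give the same outcome, so this test cannot separate it from the genotype.

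A value of 0 beside more than 10 FPKM in both other libraries of the genotype occurred for 4 genes in each genotype, among them TPL and SHD in wox5-1 and DWF1 in Col-0.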
